A study of Homo sapiens with 56 samples.

How the data were processed

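The series compared chromatin binding in HAP1 cells, a near-haploid human cell line, across wild-type cells and knockouts of subunits of the BAF (SWI/SNF) chromatin remodelling complex. Per the labels, 24 libraries were made by ChIPmentation, in which a sequencing transposase adds the adapters to immunoprecipitated chromatin, from wild-type clones 1102-3 and 921-7, and 32 libraries were made by ChIP-seq. The ChIP-seq libraries comprised 18 from wild-type clone C631 and 14 from 7 knockouts, each knockout with 1 ARID1A immunoprecipitation (IP) and 1 input library. The labels give no clone for the knockouts, whose samples were deposited apart from the wild-type ones. Batch therefore cannot be told apart from knockout in comparisons with wild type. The 56 samples formed 33 groups by assay, antibody and genotype, all read from the sample labels.

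The deposited table holds whole-number read counts, not normalised, for 145730 peaks in 58 columns. Of these columns, 2 matched no sample in the labels and were not used here. The submitters' processing notes name Bowtie2 2.2.4 for alignment, Picard 1.118 and the hg19 genome build, and all coordinates are hg19 as in the table. The role of Picard, the peak caller, the way peaks were merged into 1 list and the counting tool are not given in the sources used here. The peaks' end minus start ran from 438 to 3982 bases with a median of 622 bases. Because the list was fixed before counting, reads outside it are not analysed here, and a library's total is its total over these peaks. An annotation of hg19 was not used here, so peaks are named by position and by the histone marks measured on them, and no gene lists, cell type markers or GC content were tested.

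Counts were tested with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1 and the data.table package, version 1.17.8. Peaks were kept by filterByExpr, libraries were scaled by TMM, and the quasi-likelihood F test was applied with Benjamini-Hochberg adjustment over the peaks of each comparison. A peak was called enriched at an adjusted p under 0.05 and a fold of at least 2 over the control, and changed at an adjusted p under 0.05. Adjusted p-values in the text come from this test unless DESeq2 1.42.0 is named. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of F. Where a group had 1 library, its spread was taken from the other groups in the fit, so that library is assumed to vary like them.

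The fits were fixed before the data were examined, except for the inputs. The plan held 4 wild-type input libraries, which were summed to 2 samples only after their counts were compared. Each ChIPmentation mark was compared with IgG in 1 fit over all ChIPmentation groups, with 145115 peaks tested and 14 residual degrees of freedom. Each wild-type ChIP-seq antibody was compared with input, with 119135 peaks and 5 residual degrees of freedom. The ARID1A and ARID1B libraries (cBAF form) were compared with the ARID2 and PBRM1 libraries (PBAF form), with 51452 peaks and 4 residual degrees of freedom. ARID1A was compared with ARID1B, and SMARCA4 with SMARCA2, among the wild-type IPs, with 113755 peaks and 4 residual degrees of freedom. The ARID1A IP of each knockout was compared with the wild-type ARID1A IPs, and with the mean of the other knockouts' ARID1A IPs leaving out the ARID1A knockout, with 129397 peaks and 4 residual degrees of freedom. The ChIPmentation clones were compared with the antibody as a term, with 141081 peaks and 13 residual degrees of freedom.

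Replicates were compared before use by a chi-square test over peaks with at least 10 reads in the pair. Over 38 pairs the chi-square per degree of freedom ran from 0.998 to 4.18. The wild-type inputs 1x and 8x agreed within sampling noise, as did inputs 20 and 25, while the other input pairs did not, so these were summed to 2 input samples. The 3 libraries of H3K27ac clone 1102-3 that carry the same replicate number, 1, were summed as well, because a shared number was read as 1 sample. The labels do not say what sets them apart, and their 3 pairs differed beyond sampling noise (chi-square per degree of freedom 1.93 to 3.32). Kept apart, they gave 29775 peaks enriched for H3K27ac, against 35793, and 24 peaks between the clones, against 18. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

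Peaks were put into chromatin classes by the ChIPmentation marks enriched on them. Peaks with H3K4me3 were promoter-like, and the others with both H3K4me1 and H3K27ac were enhancer-like. The remaining peaks were assigned in the order H3K27me3, H3K9me3, H3K36me3, CTCF, H3K4me1 only and H3K27ac only, and the rest had no mark enriched. For each library the share of its counts in SMARCA4-bound peaks was given with an exact 95% Clopper-Pearson interval. The enhancer-minus-promoter value of a library was the mean over enhancer-like peaks of log2((CPM + 0.5)/(input CPM + 0.5)) minus that over promoter-like peaks, compared between cBAF and PBAF libraries by a two-sided exact permutation test. Intervals and floors cover counting error only.

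Coverage of the X chromosome was taken as X counts over autosome counts, divided by the median of the knockout inputs. It fell below 0.9 in 8 wild-type ChIP-seq libraries (0.649 to 0.812) and lay between 0.927 and 1.04 in the other 24. These 8 libraries were ARID1A replicate 1, SMARCA4 replicate 1, IgG replicate 1, inputs 1x and 8x, and the only BRD4, H3K27ac and PolII libraries. The 2 sets were treated as technical batches, and values from the full-coverage libraries alone are given beside the pooled ones. Once the input pair was summed, the reduced-coverage batch held 1 sample per group, too few for a value of its own. With full-coverage libraries alone, only the 2 ARID2 libraries, made with different antibodies, shared a group, so the fits over subunits, wild-type IPs and knockout IPs had 1 residual degree of freedom and rest on the spread of that pair. The cBAF and PBAF fit had 3. Input counts in bins of 10 Mb with at least 500 reads were used to compare the batches along the chromosomes. A gained segment was a run of at least 3 bins of 1 Mb in which a knockout's input exceeded the other knockouts' inputs 1.5-fold. A lost run was at least 3 neighbouring peaks with no read in the IP and input of a knockout where at least 20 were expected; for the ChIPmentation clones and wild-type ChIP-seq, up to 1% of the expected reads was allowed. The interval of the gained segment came from 1000 resamples of its peaks.

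Named peaks were the 5 with the largest change in each direction among those past the threshold, with a mean of at least 1 CPM and no overlap between the sides. Peaks named outside this rule are said to have been chosen after their values were seen. A fold against a group with no count was computed against a floor of 3 counts over the group and given as at least that fold.

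Alternatives covered DESeq2's Wald test, its size factors within edgeR, total counts as scaling, no filter on low counts, a stricter adjusted p of 0.01, a minimum fold of 4, IgG as control, replicate number or clone as a term, IP over own input, other peak sets and pseudocounts of 0.1 and 2. Each library was also left out in turn. Alternatives on X coverage, on autosomes alone for the knockout comparisons, on IP over own input against the other knockouts and on ARID1B alone were chosen after seeing the data. The inputs kept apart, as in the plan, became an alternative once the input pairs had been compared.

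The procedure was tested on simulated counts with 200 peaks changed by known folds, 100 of them by 2-fold and 100 by 4-fold. Of the peaks changed 4-fold it recovered 13% for H3K4me3 over IgG (143188 peaks tested), 51% for ARID1A over input (113060 peaks) and 68% for cBAF against PBAF (45002 peaks). It recovered 12% for ARID1A against ARID1B (106216 peaks) and 14% for SMARCA4 against SMARCA2 (106740 peaks). For the SMARCA4 knockout it recovered 22% against wild type (126701 peaks) and 38% against the other knockouts (124872 peaks), and for the clones 73% (138064 peaks). Of the peaks changed 2-fold it recovered between 0% (H3K4me3, SMARCA4 against SMARCA2 and the SMARCA4 knockout against wild type) and 16% (the clones). The spread of the simulated counts was estimated without TMM, and recovery was counted by adjusted p alone, without the minimum fold. The recovered shares are therefore only a guide to the real fits. Figures were drawn with matplotlib 3.10.9 and tables handled with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.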

Results

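The data cover 56 libraries from HAP1 cells, counted over 145730 peaks. HAP1 is a near-haploid human line, so a gene can be removed by disrupting a single copy. ChIPmentation of wild-type cells gave, after summing 3 libraries with the same replicate number, 4 H3K27ac libraries, 2 of H3K27me3, 3 each of H3K36me3, H3K4me1, H3K4me3, H3K9me3 and IgG, and 1 of CTCF. ChIP-seq of wild-type cells gave 2 libraries each of ARID1A, ARID2, SMARCA4 and IgG, and 1 each of ARID1B, PBRM1, SMARCA2, BRD4, H3K27ac and RNA polymerase II (PolII). The 4 wild-type inputs counted as 2 samples, because inputs 1x and 8x did not differ beyond the sampling noise, nor did inputs 20 and 25. The labels number inputs 20 and 25 as replicates 1 and 2, so counts with the inputs kept apart are given in the closing sections. Each of 7 knockouts (ARID1A, ARID1B, BCL7B, SMARCA2, SMARCA4, SMARCC1 and SMARCC2) had 1 ARID1A IP and 1 input, so no knockout had a replicate. Total counts ran from 153125 to 9510797 (median 2086297) in ChIPmentation, from 846726 to 6331069 (median 1413458) in wild-type ChIP-seq and from 907851 to 2297563 (median 1599657) in the knockouts. The 3 ChIPmentation IgG libraries were shallow, with 153125, 723332 and 876349 counts.

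Coverage of chromosome X split the ChIP-seq libraries. Relative to the knockout inputs it was 0.649 to 0.812 in 8 wild-type libraries and 0.927 to 1.04 in the other 24. Between the wild-type inputs of both sets, all 16 bins of 10 Mb on X had a ratio of 0.740 to 0.818 (median 0.784), while 288 autosomal bins had 0.847 to 1.14 (median 0.999). Because the 8 libraries included ARID1A replicate 1 and SMARCA4 replicate 1, comparisons were repeated with full-coverage libraries alone. In those fits, except that of cBAF against PBAF, the spread came from the 2 ARID2 libraries only (1 residual degree of freedom), and the 2 were made with different antibodies. Their chi-square per degree of freedom was 1.04. It was 1.61 for the ARID1A pair and 1.36 for the SMARCA4 pair, which span both X coverage sets. The ARID2 spread may therefore be too small for other IPs, which would raise the counts in these fits, those of the knockouts included.

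**Figure D1:**
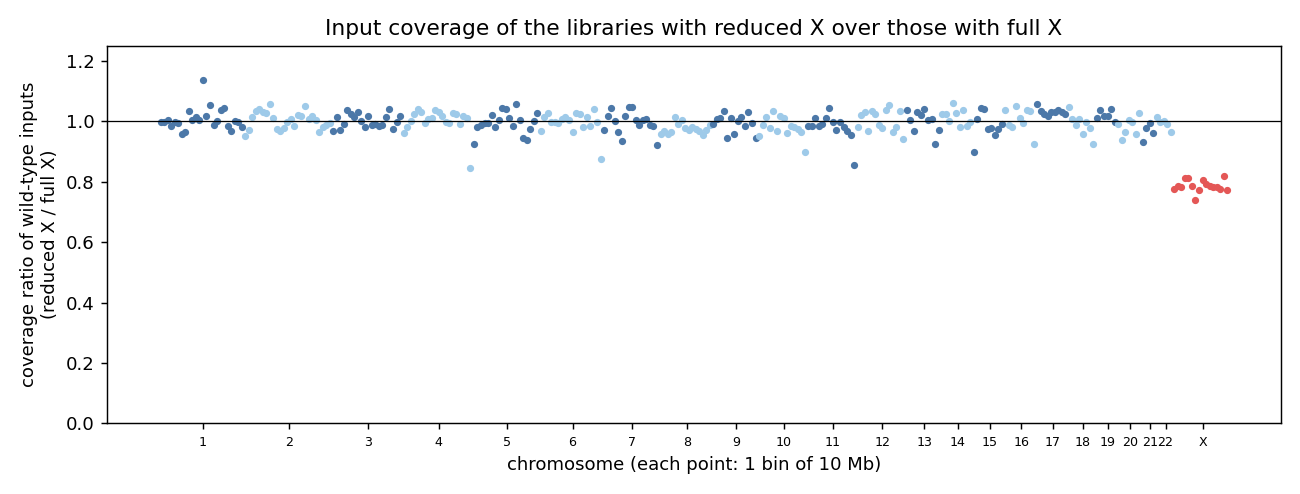
Points give, for each 10 Mb bin, the share of wild-type input counts in the reduced-coverage inputs divided by that in the full-coverage inputs, along the chromosomes. The 16 bins of chromosome X lie at 0.740 to 0.818 and the 288 autosomal bins around a median of 0.999.

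The first question was which chromatin the peaks lie in. H3K4me3, the mark of active promoters, was enriched over IgG on 36746 peaks, and H3K27ac, a mark of active promoters and enhancers, on 35793. H3K4me1, which marks enhancers and promoter flanks, was enriched on 38748 peaks, CTCF, the insulator protein, on 24784, and H3K36me3, found over transcribed gene bodies, on 17400. The repressive marks H3K27me3 and H3K9me3 were enriched on 11478 and 2282 peaks. Folds against no IgG count are lower bounds, so the order of such peaks is not exact. The highest H3K4me3 fold was at chromosome 10, 124913423 to 124914810, with 298 CPM (n = 3) against no IgG count (n = 3), at least 334-fold, and the same peak carried H3K27ac at 78.1 CPM (n = 4), at least 87.7-fold. A second peak with both marks, at chromosome 9, 136214273 to 136215469, had 267 CPM of H3K4me3, at least 300-fold, and 85.3 CPM of H3K27ac, at least 95.8-fold. The highest H3K36me3 folds were at chromosome 7, 75046117 to 75046618 (164 CPM, at least 184-fold) and at chromosome 17, 43011204 to 43011705 (162 CPM, at least 182-fold). CTCF, with 1 library, was highest at chromosome 17, 41560860 to 41561593 (155 CPM, at least 174-fold), and H3K27me3 at chromosome 12, 99288807 to 99289621 (50.8 CPM, n = 2, at least 57.1-fold). H3K4me1 was highest at chromosome 1, 10277602 to 10278555 (24.9 CPM, at least 27.9-fold), and H3K9me3 at chromosome 2, 4722272 to 4722773 (16.2 CPM, at least 18.2-fold).

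The counts of enriched peaks depended on how libraries were scaled. Depleted peaks numbered 5326 for CTCF, 6123 for H3K27ac, 7908 for H3K27me3, 6637 for H3K36me3, 24430 for H3K4me1, 16124 for H3K4me3 and 2587 for H3K9me3. With total counts as scaling, enriched and depleted peaks numbered 18651 and 62022 for CTCF, 17892 and 56990 for H3K27ac, 8673 and 19520 for H3K27me3, 12141 and 51608 for H3K36me3, 17534 and 44411 for H3K4me1, 16418 and 98435 for H3K4me3, and 3596 and 2988 for H3K9me3. With DESeq2's size factors in edgeR they numbered 29031 and 735 for CTCF, 31104 and 14894 for H3K27ac, 18068 and 6999 for H3K27me3, and 22777 and 39885 for H3K4me1. The median log2 ratio over all peaks moved by -2.69 to 0.15 with total counts and by -0.65 to 0.80 with those size factors. The H3K27me3 count fell to 5370 without clone 1102-3 replicate 1, to 6891 without clone 921-7 replicate 2 and to 7211 without IgG clone 921-7 replicate 2. For H3K9me3 it fell to 1198 without clone 1102-3 replicate 1, 1431 and 735 without clone 921-7 replicates 1 and 2, 1351 without IgG clone 1102-3 replicate 1 and 1229 without IgG clone 921-7 replicate 2.

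By these marks, 36746 peaks (25.2%) were promoter-like, 4498 (3.09%) enhancer-like, 9588 (6.58%) carried H3K4me1 only and 1706 (1.17%) H3K27ac only. A further 15031 peaks (10.3%) were CTCF sites, 13717 (9.41%) carried H3K36me3, 9533 (6.54%) H3K27me3 and 1535 (1.05%) H3K9me3, and 53376 (36.6%) had no mark enriched. At a minimum fold of 4 there were 31021 promoter-like and 2953 enhancer-like peaks, and 64442 had no mark.

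**Figure D2:**
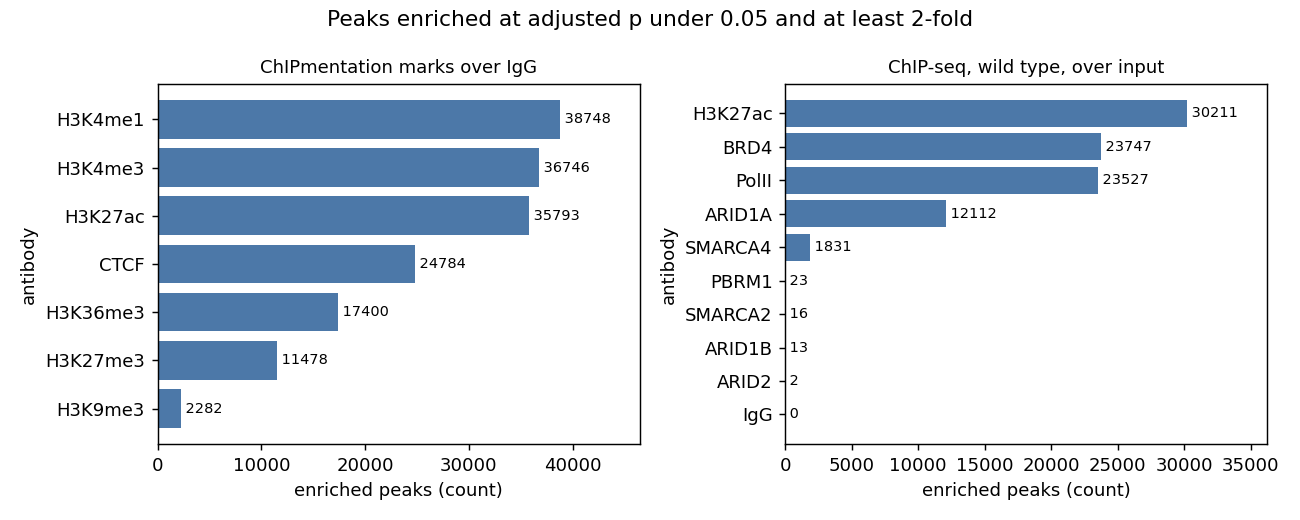
Bars give the number of peaks enriched over IgG for each ChIPmentation mark and over input for each wild-type ChIP-seq antibody, at an adjusted p under 0.05 and at least 2-fold. H3K4me1 has the tallest ChIPmentation bar (38748 peaks), and among the remodeller subunits ARID1A has 12112 peaks and SMARCA4 1831.

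The next comparison asked where each BAF subunit binds in wild-type cells. ARID1A, a subunit of the cBAF form of the complex, was enriched over input on 12112 peaks (n = 2 against 2), and SMARCA4, a catalytic ATPase, on 1831. Of the ARID1A-bound peaks, 8430 (69.6%) were promoter-like, against 30.5% of the peaks tested, and 12.6% carried H3K4me1 only, against 7.65%. Enhancer-like peaks made up 5.20% of the ARID1A-bound set, against 3.61%, and CTCF sites 0.29%, against 11.3%. Of the SMARCA4-bound peaks, 1712 (93.5%) were promoter-like. These percentages describe called peaks and were not tested across replicates.

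The promoter-like peak at chromosome 17, 65748210 to 65748851, had the highest fold for both subunits. ARID1A reached 47.4 CPM there against 2.24 in input (log2 4.37, SE 0.377, adjusted p = 3.31e-17) and SMARCA4 18.6 CPM (log2 3.02, SE 0.422, adjusted p = 2.07e-06). At chromosome 5, 139078115 to 139078776, which carried H3K27ac only, ARID1A reached log2 3.55 and SMARCA4 log2 2.65. ARID1A was also high at the promoter-like peak at chromosome 6, 69704308 to 69704897 (24.6 against 1.97 CPM, log2 3.62) and at chromosome 14, 42203535 to 42204047, with H3K4me1 only (10.8 against 0.778 CPM, log2 3.62). SMARCA4 was high at chromosome X, 137724754 to 137725255 (6.10 against 1.09 CPM, log2 2.42) and chromosome 7, 13025307 to 13025817, with H3K4me1 only (log2 2.36). Depleted peaks numbered 1655 for ARID1A and 171 for SMARCA4, and with total counts as scaling ARID1A had 9264 enriched and 3649 depleted. DESeq2 gave 3661 enriched peaks for ARID1A and 33 for SMARCA4, and the libraries with full X coverage alone gave 8378 and 562. The ARID1A count fell to 6440 without inputs 20 and 25, and the SMARCA4 count was 107 without SMARCA4 replicate 1, 3536 without replicate 2, 94 without inputs 1x and 8x, and 3 without inputs 20 and 25.

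ARID1A and SMARCA4 shared 1044 peaks, 57.0% of the SMARCA4-bound set. Independent lists of these sizes would share 186. With ARID1A called over the reduced-coverage inputs and SMARCA4 over the full-coverage ones, 1017 of 2501 SMARCA4-bound peaks were shared, where independent lists would share 189. With the inputs exchanged, 195 of 338 were shared, where independent lists would share 31.9.

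The other subunits gave few enriched peaks. ARID1B, the paralogue of ARID1A, was enriched on 13 peaks, ARID2 and PBRM1, subunits of the PBAF form, on 2 and 23, and SMARCA2, the paralogue of SMARCA4, on 16. All 16 SMARCA2-bound peaks were promoter-like, led by chromosome X, 39956694 to 39958103 (80.4 against 12.5 CPM, log2 2.68, adjusted p = 2.27e-08) and chromosome 20, 277728 to 278338 (log2 2.50). PBRM1 was highest at chromosome 19, 6108656 to 6109292 (15.4 against 2.55 CPM, log2 2.51, adjusted p = 0.0243), and 22 of its 23 peaks were promoter-like. The 2 ARID2-bound peaks, at chromosome 16, 68482178 to 68482899 (log2 1.77, adjusted p = 0.0112) and chromosome 11, 64051879 to 64053655 (log2 1.75, adjusted p = 0.0085), were promoter-like. Of the 13 ARID1B-bound peaks, 6 (46.2%) had no mark, against 30.6% of the peaks tested, and 4 (30.8%) were promoter-like, against 30.5%. They were led by chromosome 1, 231257209 to 231257710 (31.2 against 1.90 CPM, log2 4.00, adjusted p = 1.46e-09) and chromosome 1, 248266376 to 248267004 (39.8 against 3.92 CPM, log2 3.37). IgG was enriched over input on 0 peaks by edgeR (4753 at an unadjusted p under 0.05) and on 0 by DESeq2.

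DESeq2 called 0 peaks enriched for ARID1B, ARID2 and PBRM1 (503, 198 and 1082 at an unadjusted p under 0.05) and 1 for SMARCA2. With full-coverage libraries alone the counts were 37 for ARID1B, 11 for ARID2, 575 for PBRM1, 53 for SMARCA2 and 0 for IgG. Without inputs 1x and 8x or without inputs 20 and 25, respectively, edgeR gave 5 and 4 for ARID1B, 0 and 0 for ARID2, 0 and 0 for PBRM1, and 2 and 2 for SMARCA2. ARID2 gave 1 peak without the NB library and 6 without the PA5 library.

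BRD4, a reader of acetylated histones, was enriched on 23747 peaks, PolII on 23527 and the ChIP-seq H3K27ac library on 30211, each with 1 library. Promoter-like peaks made up 87.8% of the BRD4-bound set, 80.2% of the PolII-bound set and 81.3% of the H3K27ac set. H3K36me3 peaks made up 9.56% of the PolII-bound set, against 9.09% of the peaks tested. PolII reached 1059 CPM against 8.00 in input at chromosome 6, 26216463 to 26217678 (log2 7.04) and 1004 CPM against 7.91 at chromosome 10, 74079224 to 74080135 (log2 6.98). BRD4 reached 975 CPM against 24.0 at chromosome 9, 100744721 to 100747271 (log2 5.34). At chromosome 10, 48952099 to 48952676, a peak with no ChIPmentation mark, PolII was at least 57.2-fold, H3K27ac at least 22.0-fold and BRD4 at least 8.13-fold over an input without a count. Of the 30168 peaks enriched for H3K27ac by ChIP-seq and tested in both assays, 24798 (82.2%) were enriched by ChIPmentation, where independent lists would share 8800. Depleted peaks numbered 3944 for BRD4, 5135 for PolII and 19085 for H3K27ac. With total counts as scaling, which moved medians over all peaks by -2.35 to 0.01 among the wild-type antibodies, enriched and depleted peaks numbered 12505 and 68735 for BRD4, 12337 and 93818 for PolII, and 13075 and 88162 for H3K27ac, and DESeq2 gave 18146 and 68, 18771 and 106, and 23172 and 1030. All 3 libraries had reduced X coverage, so no full-coverage value exists for them.

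The cBAF and PBAF forms were compared through their ARID subunits, 3 ARID1A or ARID1B libraries against 3 ARID2 or PBRM1 libraries. Counts were higher in the cBAF libraries on 3040 peaks and higher in the PBAF libraries on 347. Of the peaks higher in cBAF, 2474 (81.4%) were promoter-like, against 59.1% of those tested, and of the peaks higher in PBAF 247 (71.2%) were promoter-like. H3K27me3 peaks made up 6.05% of those higher in PBAF, against 2.17% of those tested. Relative to the median of all peaks, SMARCA4-bound peaks had a median log2 difference of 0.62, H3K4me1-only peaks 0.25 and enhancer-like peaks 0.17 toward cBAF, while H3K27me3 peaks had -0.38 and CTCF sites -0.34. The IPs differed in strength. On SMARCA4-bound peaks the IP over input ratio was 2.31 and 2.27 for ARID1A and 1.42 for ARID1B. It was 1.36 and 1.29 for ARID2, 1.63 for PBRM1, and 1.25 and 1.20 for IgG. A difference between the forms cannot be told apart from IP strength here.

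The largest difference toward cBAF was again at chromosome 17, 65748210 to 65748851 (40.5 against 4.90 CPM, log2 3.02, SE 0.421, adjusted p = 0.00044). It was followed by chromosome 18, 33407343 to 33407971 (33.4 against 4.94 CPM, log2 2.73) and chromosome 1, 53900684 to 53901351 (log2 2.68), both promoter-like, and by chromosome 2, 81974484 to 81975275, with H3K27ac only (log2 2.67). Toward PBAF the largest differences were at chromosome 9, 116918728 to 116919392 (2.17 against 11.6 CPM, log2 -2.51, adjusted p = 0.00277), at chromosome 20, 47139579 to 47140230 (log2 -2.28) and at chromosome 1, 153394846 to 153395416 (log2 -2.22). The ARID2-bound peak at chromosome 16, 68482178 to 68482899, was also higher in PBAF (6.79 against 32.1 CPM, log2 -2.20). The total of 3387 peaks became 1830 by DESeq2, 2188 (2053 and 135) with full-coverage libraries alone, which leaves out ARID1A replicate 1, and 1304 without ARID1A replicate 2. It was 9040 without ARID1B, 1773 without the NB library of ARID2, 994 without the PA5 library and 3 without PBRM1. ARID1B alone against the PBAF antibodies differed on 8 peaks.

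The balance of enhancers to promoters was also compared between both forms. The enhancer-minus-promoter value was -0.14 (SD 0.16, n = 3) for the cBAF libraries and -0.11 (SD 0.065, n = 3) for the PBAF libraries. The IgG libraries had -0.176 and -0.0105 by this measure. The ARID1B (-0.009), ARID2 (-0.0772 and -0.0635) and PBRM1 (-0.183) libraries lay within or close to that range. The comparison therefore rests largely on libraries near background. The difference of -0.037 was smaller than the spread between libraries (two-sided exact permutation test over 20 assignments, p = 0.8, where the smallest possible is 0.1). Its sign turned without ARID1A replicate 1 (0.051), which is also the value from full-coverage libraries alone, and with classes set at a minimum fold of 4 (0.078). Over own inputs it turned as well, with -0.26, -0.16 and -0.063 for cBAF and -0.13, -0.12 and -0.24 for PBAF, whose means nearly coincide.

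ARID1A and ARID1B, which occupy the same position in cBAF, were compared directly. ARID1A was higher on 823 peaks and ARID1B on 38 (n = 2 against 1). The ARID1B IP was the weaker. Its IP over input ratio on SMARCA4-bound peaks was 1.42, against 2.31 and 2.27 for ARID1A and 1.25 and 1.20 for IgG. Where ARID1A was higher, a difference between the paralogues cannot be told apart from IP strength here. Where ARID1B was higher, the difference rests on 1 ARID1B library, and its cause was not tested. Of the peaks higher for ARID1A, 681 (82.8%) were promoter-like, against 31.8% of those tested, while 55.3% of those higher for ARID1B had no mark. Relative to all peaks, the median log2 difference toward ARID1A was 0.41 on promoter-like, 0.32 on H3K4me1-only and 0.26 on enhancer-like peaks. On H3K27me3 peaks it was -0.55. ARID1B had no count at chromosome 18, 52668731 to 52669442, with H3K4me1 only (37 ARID1A counts, at least 4.95-fold), nor at the enhancer-like peak at chromosome 4, 124529276 to 124529799 (33 counts, at least 4.28-fold). ARID1B was higher at chromosome 1, 248266376 to 248267004 (1.68 CPM for ARID1A against 38.4, log2 -4.54, SE 0.511, adjusted p = 2.55e-10), and ARID1A had no count at chromosome 1, 71620124 to 71620625 (at least 6.58-fold).

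DESeq2 called 0 of these differences (1993 at an unadjusted p under 0.05, against 14886 by edgeR), and full-coverage libraries alone gave 1165. The count of 861 was 315 without ARID1A replicate 1, 3726 without ARID1A replicate 2, 461 with DESeq2's size factors and 193 (161 and 32) with total counts, where 83.4% were higher for ARID1A, against 95.6% by the planned scaling, and the median of all peaks moved by -0.21. SMARCA4 and SMARCA2 (n = 2 against 1), the alternative ATPases of the complex, differed on 0 peaks by edgeR (8410 at an unadjusted p under 0.05) and on 0 by DESeq2 (628). They differed on 10 with full-coverage libraries alone and on 7 without SMARCA4 replicate 2. Promoter-like peaks had a median log2 difference of 0.36 toward SMARCA4 relative to all peaks, and IP strength was not separated here either. A replicate block, given in the closing sections, raised the counts of both paralogue comparisons.

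The knockouts asked how ARID1A binding depends on each BAF subunit. The share of ARID1A IP counts in the 1831 SMARCA4-bound peaks was 5.26% (95% interval 5.22 to 5.29) and 4.63% (4.60 to 4.66) in the 2 wild-type replicates, against 2.28% and 2.04% in their inputs. In the ARID1A knockout it was 2.15% (2.13 to 2.18), close to the 2.12% of its input. BCL7B knockout cells had 2.71%, against 2.61% in input, SMARCC1 knockout cells 2.57%, against 2.10%, and SMARCA2 knockout cells 2.90%, against 2.15%. The SMARCA4 (3.88%, input 2.17%), ARID1B (3.95%, input 2.30%) and SMARCC2 (4.08%, input 2.22%) knockouts also lay below the lower wild-type replicate. Every knockout did so, and deposit batch cannot be told apart from knockout here. The IP over input ratio was 2.31 and 2.27 in wild type, 1.02 in the ARID1A knockout, 1.04 for BCL7B, 1.22 for SMARCC1, 1.35 for SMARCA2, 1.72 for ARID1B, 1.79 for SMARCA4 and 1.84 for SMARCC2. IgG reached 1.25 and 1.20 by the same measure.

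The order of the knockouts depended on the peaks used. Over the 12112 ARID1A-bound peaks the IP over input ratio was 2.86 and 2.69 in wild type, 1.02 in the ARID1A knockout, 1.16 for SMARCC1, 1.40 for SMARCA2, 1.54 for BCL7B, 1.55 for SMARCA4, 1.91 for SMARCC2 and 2.27 for ARID1B, and IgG had 1.19 and 1.26. These peaks were chosen in the wild-type ARID1A libraries over the wild-type inputs, a choice that favours wild type. The SMARCA4-bound peaks were chosen over the same wild-type inputs, so the wild-type ratios are favoured there as well. The ratio of the BCL7B knockout on SMARCA4-bound peaks rests on the highest share of any input, and at a minimum fold of 4 its IP had 0.0441% against 0.0196% in input. On ARID1A-bound peaks the SMARCA4 knockout (14.6% of counts) lay beside SMARCA2 (14.3%) and BCL7B (13.0%) rather than beside ARID1B (19.1%) and SMARCC2 (19.6%). The ARID1A knockout, with 9.44% against 9.26% in its input, had the lowest ratio in both sets, and no knockout label was checked further here.

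**Figure D3:**
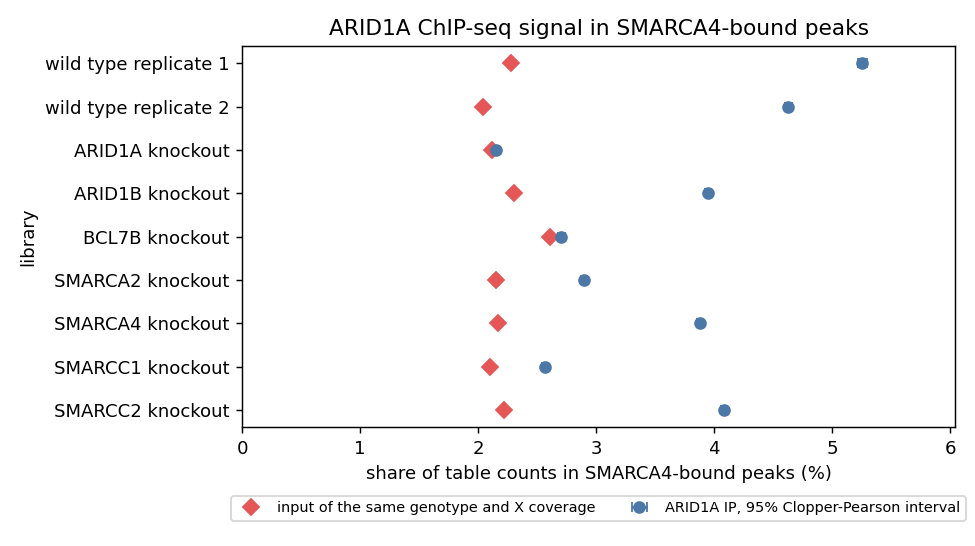
Points give the percentage of each library's counts that lie in the 1831 SMARCA4-bound peaks, for the ARID1A IP and the input of each genotype, with 95% binomial intervals. The wild-type IPs sit at 5.26% and 4.63%, the ARID1A knockout IP at 2.15% beside its input at 2.12%, and the other knockouts in between.

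Against the wild-type ARID1A IPs, counts were lower on 6762 peaks in the ARID1A knockout, 3733 in SMARCC1, 2277 in SMARCA4, 1383 in BCL7B, 156 in SMARCA2, 18 in ARID1B and 5 in SMARCC2 knockout cells. They were higher on 827, 349, 122, 81, 3, 2 and 0 peaks in the same order. Any effect of the deposit batch is part of these counts too. Most peaks that fell were promoter-like, 79.8% in the ARID1A, 82.5% in the BCL7B, 81.4% in the SMARCA2, 78.8% in the SMARCC1 and 70.1% in the SMARCA4 knockout, against 28.2% of those tested. In the SMARCA4 knockout 12.3% carried H3K4me1 only, against 7.25%, and 5.80% were enhancer-like, against 3.39%. These shares, and its promoter-like share, lay close to those of the ARID1A-bound peaks given above. They therefore do not show that these classes lost more ARID1A signal than other bound peaks. Of the peaks higher in the ARID1A knockout, 53.5% had no mark, a class with 42871 of the 129397 peaks tested, and 18.6% carried H3K27me3, against 5.75% of those tested. The IP of this knockout had 1.02 times its input's share in SMARCA4-bound peaks. Its higher counts therefore do not show a gain of ARID1A binding. Relative to the median of all peaks, promoter-like peaks had a median log2 change of -0.73 in the ARID1A, -0.66 in the SMARCC1, -0.60 in the BCL7B, -0.48 in the SMARCA2, -0.21 in the SMARCA4, -0.21 in the ARID1B and -0.18 in the SMARCC2 knockout. On H3K4me1-only peaks the SMARCA4 knockout, at -0.52, lay beside the ARID1A (-0.54) and SMARCC1 (-0.49) knockouts, and the BCL7B (-0.31), SMARCA2 (-0.27), ARID1B (-0.18) and SMARCC2 (-0.077) knockouts moved less.

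**Figure D4:**
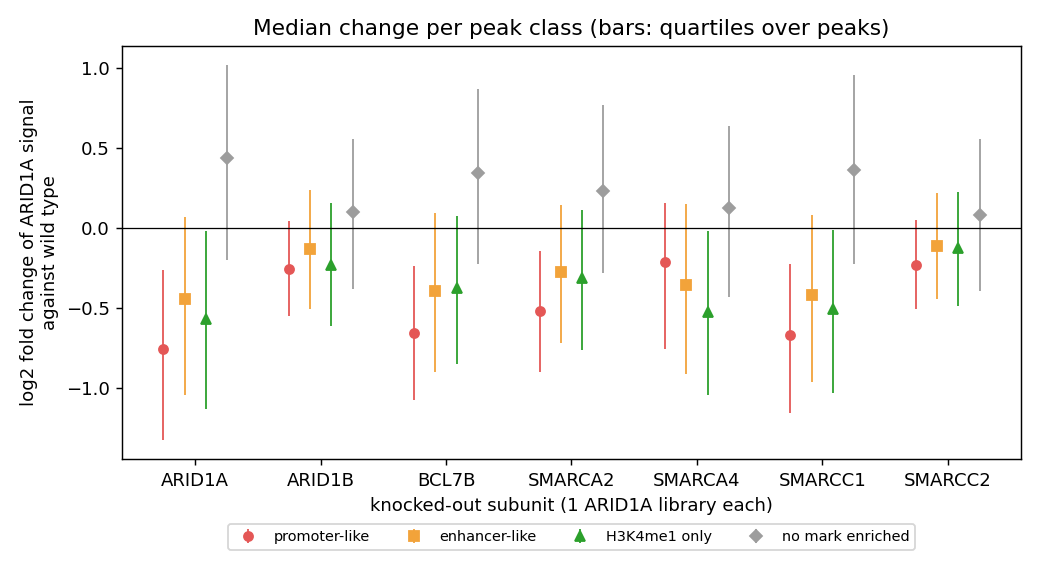
Points give the median log2 change of the ARID1A IP in each knockout against wild type for each chromatin class, and bars span the quartiles over peaks. Promoter-like peaks lie lowest in the ARID1A knockout (-0.75), while in the SMARCA4 knockout they lie at -0.21, and total counts as scaling raise the median of all peaks by 0.11 to 0.28.

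ARID1A knockout cells had no count at chromosome 13, 78967429 to 78968073, against 33 in wild type (at least 5.61-fold), or at the promoter-like peak at chromosome 17, 20255788 to 20256334 (at least 4.87-fold). SMARCA4 knockout cells had none at the enhancer-like peak at chromosome 10, 60828208 to 60828801 (at least 4.84-fold). In ARID1B knockout cells the promoter-like peaks at chromosome 4, 61348442 to 61349241 (2.00 against 32.0 CPM, log2 -3.94, SE 0.578, adjusted p = 0.000275), chromosome 11, 38051825 to 38052712 (log2 -3.77) and chromosome X, 21001378 to 21002008 (log2 -3.54) were lower. BCL7B knockout cells had no count at the enhancer-like peak at chromosome 4, 95004789 to 95005853 (at least 8.56-fold). SMARCA2 knockout cells had none at chromosome 2, 15158842 to 15160234 (at least 17.1-fold) and chromosome 4, 95471919 to 95472625 (at least 16.2-fold), SMARCC1 knockout cells none at chromosome 9, 82277283 to 82279851 (at least 21.2-fold), and SMARCC2 knockout cells none at chromosome 1, 6926754 to 6928425 (at least 29.5-fold) and chromosome 2, 205535284 to 205536123 (at least 18.3-fold). The inputs of these 3 knockouts lacked reads at the last 5 peaks too, so these folds do not show a loss of ARID1A binding. Such runs of peaks without input reads held 6 of the 156 lower peaks in SMARCA2, 21 of 3733 in SMARCC1, 4 of 5 in SMARCC2 and 2 of 1383 in BCL7B. Lower peaks without a read in both IP and input occurred in every knockout except ARID1B, with most in SMARCC1, followed by SMARCA2. In the SMARCC1, SMARCA2 and BCL7B knockouts they outnumbered the lower peaks in such runs.

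DESeq2 called 0 peaks in each of these 7 comparisons, with 4768 (ARID1A), 197 (ARID1B), 2081 (BCL7B), 1223 (SMARCA2), 1872 (SMARCA4), 2967 (SMARCC1) and 116 (SMARCC2) at an unadjusted p under 0.05. With each IP set over its own input, edgeR called 1145 in the ARID1A knockout, 42 in BCL7B, 6 in SMARCA4, 4 in SMARCC1 and 0 in ARID1B, SMARCA2 and SMARCC2. With full-coverage libraries alone, which keep wild-type replicate 2, lower and higher peaks numbered 7730 and 997 (ARID1A), 267 and 44 (ARID1B), 3256 and 237 (BCL7B), 2303 and 102 (SMARCA2), 3496 and 342 (SMARCA4), 5528 and 579 (SMARCC1), and 9 and 2 (SMARCC2). Without wild-type ARID1A replicate 1 alone, the sums of both directions were 76 for ARID1B and 835 for BCL7B. Without replicate 2 they were 375 for ARID1B, 5346 for BCL7B, 3459 for SMARCA2, 5344 for SMARCA4, 7673 for SMARCC1 and 588 for SMARCC2. With total counts as scaling the median of all peaks moved up by 0.11 to 0.28, and the higher share rose from 10.9% to 30.3% for ARID1A (1686 against 3871 lower), from 5.53% to 18.4% for BCL7B (52 against 231) and from 8.55% to 25.2% for SMARCC1 (491 against 1460).

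Each knockout was then set against the other knockouts, leaving out ARID1A. Of the 129397 peaks tested, 36487 were promoter-like. On SMARCA4-bound peaks the IP over input ratio was 1.79 for the SMARCA4, 1.84 for the SMARCC2 and 1.72 for the ARID1B knockout. It was 1.04 for BCL7B, 1.22 for SMARCC1 and 1.35 for SMARCA2. Where the SMARCA4, SMARCC2 and ARID1B knockouts were higher, a difference cannot be told apart from IP strength here. SMARCA4 knockout cells had 212 peaks higher and 22 lower, and 60.9% of the higher peaks were promoter-like. ARID1B knockout cells had 39 peaks higher and 1 lower, SMARCC2 knockout cells 30 and 6, SMARCC1 knockout cells 1 and 8, and SMARCA2 knockout cells 0 and 7. ARID1A and BCL7B knockout cells differed on 0 peaks by edgeR (11002 and 6683 at an unadjusted p under 0.05). The SMARCA4 knockout was higher at the promoter-like peak at chromosome 5, 52293139 to 52293768 (35.5 against 6.24 CPM, log2 2.72, SE 0.358, adjusted p = 8e-06) and at chromosome 20, 51116603 to 51117277 (log2 2.64, adjusted p = 0.000102). It had no count at the enhancer-like peak at chromosome 10, 60828208 to 60828801 (at least 3.89-fold lower). The ARID1B knockout was higher at chromosome 12, 102046827 to 102047796, with H3K4me1 only (41.5 against 8.16 CPM, log2 2.54, SE 0.325, adjusted p = 3.69e-06), and lower at chromosome 21, 23084151 to 23085519 (log2 -2.97). The SMARCC2 knockout was higher at the promoter-like peak at chromosome X, 21001378 to 21002008 (17.8 against 4.72 CPM, log2 2.24), and 26 of its 30 higher peaks were promoter-like.

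Of the lower peaks, 4 of 7 in the SMARCA2, 6 of 8 in the SMARCC1 and 4 of 6 in the SMARCC2 knockout lay in runs where the input also lacked reads, and 8 of the 39 higher peaks of the ARID1B knockout lay at the end of chromosome X where its input was raised. DESeq2 called 0 peaks in each of these comparisons (ARID1A 591, ARID1B 183, BCL7B 167, SMARCA2 103, SMARCA4 517, SMARCC1 237 and SMARCC2 135 at an unadjusted p under 0.05). With each IP over its own input edgeR called 30 for ARID1A, 2 for BCL7B and 0 for the other 5. With full-coverage libraries alone, which leaves out only wild-type IPs and takes its spread from the 2 ARID2 libraries, the counts were 822 for ARID1A, 1883 for ARID1B, 8 for BCL7B, 10 for SMARCA2, 2201 for SMARCA4, 44 for SMARCC1 and 2440 for SMARCC2. Leaving out single knockouts gave, for SMARCA4, 98 without BCL7B, 113 without SMARCA2 and 132 without SMARCC1, and for ARID1B 7 without SMARCA4, 10 without SMARCC1 and 217 without SMARCC2. For SMARCC2 it gave 134 without ARID1B, 12 without SMARCA4 and 13 without SMARCC1, and for ARID1A 1 without BCL7B, 1 without SMARCA2 and 9 without SMARCC1. With DESeq2's size factors in edgeR the SMARCC2 knockout had 15 peaks higher and 6 lower, 71.4% higher against 83.3% by the planned scaling.

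The ChIPmentation clones 1102-3 and 921-7, both wild type, were compared over all marks (9 against 12 libraries). They differed on 18 peaks, 16 higher in clone 1102-3, and 11 of these lay in 1 run of 12 peaks on chromosome 6, 163026877 to 163149232. There the promoter-like peak at 163094272 to 163095164 had 16.9 CPM in clone 1102-3 against 0.041 in clone 921-7 (log2 7.07, SE 0.601, adjusted p = 1.28e-27), and the peak at 163055064 to 163055824 had 140 counts against 0 (at least 53.7-fold). The log2 value comes from the fit with antibody as a term and is not the ratio of the CPM means. Outside it, and chosen after the values were seen, chromosome 19, 39465656 to 39466867, was higher in clone 1102-3 (log2 2.29, adjusted p = 2.63e-06) and chromosome 2, 225265492 to 225267100, lower (log2 -1.60). The other lower peak, at chromosome 16, 78830044 to 78830545, lay at the end of a run of 4 peaks that clone 1102-3 lacked (at most 1% of the expected reads). DESeq2 called 4 peaks, all higher in clone 1102-3. The share higher was 88.9% by the planned scaling, 71.4% with DESeq2's size factors (15 and 6) and 60.0% with total counts (18 and 12), which moved the median of all peaks by -0.16 and -0.21. The count was 10 without H3K27ac clone 921-7 replicate 2, 11 without H3K27ac clone 1102-3 replicate 1, 42 and 50 without H3K27me3 clone 1102-3 replicate 1 and clone 921-7 replicate 2, 10 and 11 without H3K4me1 clone 1102-3 replicate 2 and clone 921-7 replicate 2, and 9 and 10 without H3K4me3 clone 1102-3 replicate 1 and clone 921-7 replicate 2.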

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

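The tests of missing DNA, of the run on chromosome 6, of the end of chromosome X, of X coverage and of H3K4me1-only peaks in the SMARCA4 knockout, and the alternatives on X coverage and on own inputs against the other knockouts, were chosen only after the results were seen, as was the test of other splits for H3K27ac. The results below stood apart because 1 knockout's ARID1A signal differed from that of the other knockouts by a test of the difference itself, or because an input library showed a signal outside the comparisons. ARID1A counts in the SMARCA4 knockout differed from the other knockouts on 234 peaks by edgeR, in the ARID1B knockout on 40, in the SMARCC2 knockout on 36, in the SMARCC1 knockout on 9 and in the SMARCA2 knockout on 7. Each knockout was 1 library whose spread came from other groups, DESeq2 called 0 peaks in each of these 5 comparisons, and with the IP over its own input edgeR called 0. IP strength also differed between the knockouts and was not separated from these differences. The input of the ARID1B knockout had 2.11 times the coverage of the other knockouts' inputs on chromosome X, 149000605 to 154892419.

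In the SMARCA4 knockout, median ARID1A signal against wild type was lower on H3K4me1-only peaks (-0.52 relative to all peaks) than on promoter-like peaks (-0.21), the opposite order to the other 6 knockouts by this measure. Weaker immunoprecipitation stays open, because over own input the H3K4me1-only minus promoter-like signal lay 0.257 below the lower wild-type replicate, less than the range of 0.538 among the other 6 knockouts. Uneven coverage of its own input stays open by the same range, although the signal of -0.346 lay below the lowest other knockout, SMARCC2 at -0.146, which was itself below both wild-type libraries (-0.089 and -0.011). So does chance between single libraries, since the 2 wild-type ARID1A libraries differed by 0.169 over wild-type input, where the gap to the next knockout was 0.202, and by 0.078 over own input, where it was 0.199. A dependence of ARID1A at H3K4me1-marked sites on the SMARCA4 ATPase is open as well, and with 1 library it was not tested.

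The 21 peaks lower in the SMARCA2, SMARCC1 or SMARCC2 knockout than in the other knockouts had 3 reads in their own inputs where 346.8 were expected, and 14 of them lay in lost runs. Missing DNA in those clones, rather than a loss of ARID1A binding, is therefore a candidate explanation for these peaks. It was argued against for the 22 lower peaks of the SMARCA4 knockout, whose input had 301 reads where 327.1 were expected. For the raised end of chromosome X in the ARID1B knockout, stronger ARID1A binding is argued against, since the IP rose 1.94 times and, relative to the input, to 0.917 (95% interval 0.881 to 0.956 from resampled peaks). An extra copy of that segment, 1.99 times the wild-type inputs (1.92 to 2.05), stays open and was not tested by another assay.

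The reduced X coverage of 8 wild-type ChIP-seq libraries also separated libraries of the same antibody. An antibody that avoids X is argued against, because inputs were affected, at 0.775 or less. Loss of a part of X is argued against by the highest of its bins at 0.818, and a bias that also acts on autosomes by the lowest autosomal bin at 0.847. Loss of X from part of the cells stays open and was not tested, and no biological explanation is given by the design. With X coverage as a term the cBAF and PBAF libraries differed on 1798 peaks, against 3387 without it.

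Other splits of the same libraries were counted for each comparison of at least 3 samples a side. For H3K27ac over IgG the real split gave 35793 peaks and the highest of the other splits 267, so 1 of 35 splits reached the real value, a share under 0.05. Every other split mixed H3K27ac and IgG libraries in at least 1 group, which widens the spread there and leaves few calls. Low counts in the other splits were therefore built in, and these splits cannot decide whether chance played a part. For the comparisons with 10 splits, 1 reached the real value in each, and the splits are too few for a share under 0.05. The real value and the highest other were 17400 and 3282 for H3K36me3, 38748 and 94 for H3K4me1, 36746 and 1 for H3K4me3, 2282 and 4 for H3K9me3, and 3387 and 0 for cBAF against PBAF. For the clones, 3 of 30 splits gave at least the real 18 peaks, so chance cannot be excluded for that count as a whole, and the highest, at 90, points to a structure of the samples that was not tested. Chance is excluded for the 11 of these peaks in the run on chromosome 6, where the 12 libraries of clone 921-7 had 9 reads and 3924 were expected.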

How the results depend on the processing

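The alternatives on X coverage, on ARID1B alone, on autosomes in the knockout comparisons and on IP over own input against the other knockouts were tried only after the data were seen. The inputs kept apart, as in the plan, became an alternative after the input pairs were compared. No count is signed, and the enhancer-minus-promoter difference was the only summary value that turned. The cause was not tested for any value below unless the setting itself uses fewer peaks or libraries. Values of the 258 named peaks under other settings kept direction and threshold in 1803 cases and direction only in 376. By DESeq2's Wald test 104 of 258 kept the threshold, and with each IP over its own input 3 of 97 did. In 2 cases they turned, both with the IP over its own input, to 0.21 for the peak on chromosome 11, 16841737 to 16842452, in the SMARCA4 knockout against wild type and to 0.085 for the peak on chromosome 1, 22458173 to 22458926, in the SMARCC2 knockout against the other knockouts. These IPs had no count at their peak, so the size of the change rests on the control alone. Small changes may mostly be missed, since simulated 2-fold changes, with a spread estimated without TMM, were recovered for 0% to 16% of peaks. With pseudocounts of 0.1 and 2 the enhancer-minus-promoter difference kept its sign. The shallow IgG libraries of ChIPmentation, with 153125 to 876349 counts, limit every mark's comparison.

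With DESeq2's size factors in edgeR, 18068 peaks for H3K27me3 and 22777 for H3K4me1 were enriched over IgG. Between antibodies, 461 peaks for ARID1A against ARID1B changed. Against wild type, 286 peaks for SMARCA2 knockout changed. Among knockouts, 21 peaks for SMARCC2 changed. With total counts as scaling, 17892 peaks for H3K27ac, 17534 for H3K4me1, 16418 for H3K4me3 and 3596 for H3K9me3 were enriched over IgG. Over input, 4 peaks for ARID2, 12505 for BRD4, 13075 for H3K27ac, 58 for PBRM1 and 12337 for PolII were enriched. Between antibodies or clones, 193 peaks for ARID1A against ARID1B, 2 for SMARCA4 against SMARCA2 and 30 for clone 1102-3 against clone 921-7 changed. Against wild type, 283 peaks for BCL7B, 24 for SMARCA2, 1551 for SMARCA4 and 1951 for SMARCC1 knockout changed. Among knockouts, 1 peak for ARID1A and 23 for SMARCC2 changed. By DESeq2's Wald test, 22341 peaks for H3K4me1 were enriched over IgG. Over input, 3661 peaks for ARID1A, 0 for ARID1B, 0 for ARID2, 0 for PBRM1, 1 for SMARCA2 and 33 for SMARCA4 were enriched. Between antibodies or clones, 1830 peaks for cBAF against PBAF, 0 for ARID1A against ARID1B and 4 for clone 1102-3 against clone 921-7 changed. Counts against wild type were 0 for ARID1A, ARID1B, BCL7B, SMARCA2, SMARCA4, SMARCC1 and SMARCC2 knockout. Counts against the other knockouts were 0 for ARID1B, SMARCA2, SMARCA4, SMARCC1 and SMARCC2 knockout. With no filter on low counts, 1 peak for ARID2, 10 for PBRM1, 10 for SMARCA2 and 2861 for SMARCA4 were enriched over input. Between antibodies, 189 peaks for ARID1A against ARID1B changed. Against wild type, 55 peaks for SMARCA2 knockout changed. Among knockouts, 22 peaks for SMARCC2 changed. With IgG as control, 6999 peaks for ARID1A, 7 for ARID1B, 1 for ARID2, 6 for PBRM1, 7 for SMARCA2 and 225 for SMARCA4 were enriched over IgG. With the NB antibody of ARID2 only, 994 peaks for cBAF against PBAF changed. With the PA5 antibody of ARID2 only, 1773 peaks for cBAF against PBAF changed. With only peaks bound by a tested subunit, 5777 peaks for cBAF against PBAF changed. That set holds the ARID1A-bound peaks, which were chosen in ARID1A libraries of this comparison, so the choice favours cBAF. The same ARID1A-bound peaks, used next, were chosen in the wild-type libraries, so that choice favours lower counts in the knockouts. With only ARID1A-bound peaks, 136 peaks for ARID1B, 6525 for BCL7B, 4637 for SMARCA2, 5735 for SMARCA4, 8560 for SMARCC1 and 3 for SMARCC2 knockout changed against wild type. With only SMARCA4-bound peaks, 1175 peaks for ARID1A, 8 for ARID1B, 958 for BCL7B, 820 for SMARCA2, 376 for SMARCA4, 1039 for SMARCC1 and 0 for SMARCC2 knockout changed against wild type. With each IP over its own input, 1145 peaks for ARID1A, 42 for BCL7B, 6 for SMARCA4 and 4 for SMARCC1 knockout changed against wild type, and 0 for ARID1B, SMARCA2 and SMARCC2. Among knockouts, 30 peaks for ARID1A and 2 for BCL7B changed, and 0 for ARID1B, SMARCA2, SMARCA4, SMARCC1 and SMARCC2. At an adjusted p under 0.01, 6134 peaks for H3K27me3 and 865 for H3K9me3 were enriched over IgG. Over input, 1 peak for ARID2, 4 for PBRM1, 10 for SMARCA2 and 302 for SMARCA4 were enriched. Between antibodies, 1114 peaks for cBAF against PBAF and 61 for ARID1A against ARID1B changed. Against wild type, 3193 peaks for ARID1A, 8 for ARID1B, 16 for BCL7B, 13 for SMARCA2, 676 for SMARCA4 and 855 for SMARCC1 knockout changed. Among knockouts, 5 peaks for ARID1B, 3 for SMARCA2, 49 for SMARCA4 and 9 for SMARCC2 changed. At a minimum fold of 4, 23503 peaks for H3K4me1 were enriched over IgG. Over input, 2328 peaks for ARID1A, 0 for ARID2, 7 for PBRM1, 7 for SMARCA2 and 41 for SMARCA4 were enriched. The ARID1A share was 0.096% in wild type replicate 1, 0.0939% in wild type replicate 2, 0.0239% in ARID1A, 0.074% in ARID1B, 0.0441% in BCL7B, 0.0483% in SMARCA2, 0.0549% in SMARCA4, 0.0329% in SMARCC1 and 0.079% in SMARCC2 knockout. By a contrast of antibody group means, 1991 peaks for cBAF against PBAF changed. With classes at a minimum fold of 4, the cBAF minus PBAF difference in enhancer-minus-promoter value was 0.078. In PBRM1-bound or ARID2-bound peaks, the ARID1A share was 0.0413% in wild type replicate 1, 0.0405% in wild type replicate 2, 0.0358% in ARID1A, 0.039% in ARID1B, 0.0347% in BCL7B, 0.0352% in SMARCA2, 0.0459% in SMARCA4, 0.0363% in SMARCC1 and 0.0377% in SMARCC2 knockout. In ARID1A-bound peaks, the ARID1A share was 26.5% in wild type replicate 1, 23% in wild type replicate 2, 9.44% in ARID1A, 19.1% in ARID1B, 13% in BCL7B, 14.3% in SMARCA2, 14.6% in SMARCA4, 11.4% in SMARCC1 and 19.6% in SMARCC2 knockout. On autosomes only, the ARID1A share was 4.58% in wild type replicate 2, 3.91% in ARID1B, 3.85% in SMARCA4 and 4.05% in SMARCC2 knockout.

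With the 4 inputs kept apart, 7 peaks for ARID2, 133 for PBRM1, 25 for SMARCA2 and 3139 for SMARCA4 were enriched over input. With X coverage as a term, 51 peaks for ARID1B, 25 for ARID2, 1266 for PBRM1, 109 for SMARCA2 and 3637 for SMARCA4 were enriched over input. Between antibodies, 1798 peaks for cBAF against PBAF, 2477 for ARID1A against ARID1B and 27 for SMARCA4 against SMARCA2 changed. Against wild type, 255 peaks for ARID1B, 3746 for BCL7B, 2320 for SMARCA2, 4254 for SMARCA4, 6669 for SMARCC1 and 11 for SMARCC2 knockout changed. Among knockouts, 613 peaks for ARID1A, 1573 for ARID1B, 6 for BCL7B, 1720 for SMARCA4, 29 for SMARCC1 and 1660 for SMARCC2 changed. With full-coverage libraries alone, 37 peaks for ARID1B, 11 for ARID2, 575 for PBRM1, 53 for SMARCA2 and 562 for SMARCA4 were enriched over input. Between antibodies, 2188 peaks for cBAF against PBAF and 10 for SMARCA4 against SMARCA2 changed. Against wild type, 311 peaks for ARID1B, 3493 for BCL7B, 2405 for SMARCA2, 3838 for SMARCA4 and 11 for SMARCC2 knockout changed. Among knockouts, 822 peaks for ARID1A, 1883 for ARID1B, 8 for BCL7B, 2201 for SMARCA4, 44 for SMARCC1 and 2440 for SMARCC2 changed. With ARID1B alone against the PBAF antibodies, 8 peaks for cBAF against PBAF changed.

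The replicate numbers did not pair the samples across most antibodies. Of 6 pairs of ChIP-seq antibodies 1, ARID1A with SMARCA4 at 0.164, had a correlation of deviations above 0.1, the lowest being 0.001. Of 10 ChIPmentation pairs 0 did, at -0.012 to 0.053. The block is therefore given only here. Replicates 1 and 2 of ARID1A, SMARCA4 and IgG in ChIP-seq lay in different X coverage sets, and that split is covered by X coverage as a term. With a replicate block and the inputs kept apart, 29 peaks for ARID1B, 14 for ARID2, 1 for IgG, 369 for PBRM1, 38 for SMARCA2 and 4843 for SMARCA4 were enriched over input. With a replicate block, 5336 peaks for ARID1A against ARID1B and 196 for SMARCA4 against SMARCA2 changed, where the main fit had 861 and 0. These 2 comparisons therefore depend on whether the block is used.

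With single libraries left out, counts ranged from 5370 to 8778 for H3K27me3 over IgG, 735 to 1919 for H3K9me3 over IgG, 6440 to 11914 for ARID1A over input and 0 to 6 for ARID2 over input. They ranged from 3 to 3536 for SMARCA4 over input, 4 to 5 for ARID1B over input, 0 at each for PBRM1 over input and 2 at each for SMARCA2 over input. The range was 3 to 9040 for cBAF against PBAF, 315 to 3726 for ARID1A against ARID1B, 0 to 7 for SMARCA4 against SMARCA2 and 76 to 375 for the ARID1B knockout against wild type. The range was 835 to 5346 for the BCL7B knockout against wild type, 156 to 3459 for the SMARCA2 knockout against wild type, 2145 to 5344 for the SMARCA4 knockout against wild type and 2961 to 7673 for the SMARCC1 knockout against wild type. The range was 7 to 588 for the SMARCC2 knockout against wild type, 0 to 9 for the ARID1A knockout against the others, 98 to 281 for the SMARCA4 knockout against the others and 12 to 134 for the SMARCC2 knockout against the others. The range was 7 to 217 for the ARID1B knockout against the others and 9 to 50 for the clones. The cBAF minus PBAF difference in enhancer-minus-promoter value ranged from -0.105 to 0.0509, and only the value without ARID1A replicate 1 was above 0.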

Other observations

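No test in this part was run beyond those given above, and the peaks and classes described here were chosen after the values were seen. BRD4 and PolII had lower enhancer-minus-promoter values than ARID1A and SMARCA4, and no test of the difference was run. Over its own input, the enhancer-minus-promoter value (log2, 1 library each) was -1.07 for BRD4, -1.51 for PolII and -0.99 for ChIP-seq H3K27ac. It was -0.47 and -0.30 in the 2 SMARCA4 libraries and -0.26 and -0.16 in the 2 ARID1A libraries, while the 2 IgG libraries had -0.11 and -0.065. Over the pooled wild-type inputs SMARCA4 had -0.53 and -0.25 in replicates 1 and 2 and ARID1A -0.32 and -0.10, so SMARCA4 was lower within each X coverage set while the ranges overlapped. On H3K4me1-only peaks the mean log2 signal over own input, scaled by total counts, was 0.18 and 0.31 for ARID1A and -0.12 and 0.040 for SMARCA4, and IgG had -0.061 and 0.073. The 12112 ARID1A-bound peaks held 4.24% of PolII counts, against 9.26% of the counts of its inputs, and 9.61% of BRD4 counts. These are shares of total counts. The TMM factor was 0.248 for PolII and 0.499 for BRD4, against 1.325 for inputs 1x and 8x. The planned scaling would therefore raise both antibodies relative to input, and the shares do not show that PolII is depleted on these peaks.

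H3K9me3, a mark of constitutive heterochromatin, had more of its counts on chromosome X than other marks. X counts over autosome counts, relative to the knockout inputs, were 1.46, 1.48 and 1.50 in the 3 H3K9me3 libraries, against 1.123, 1.14 and 1.14 in IgG, 0.902, 0.976 and 0.987 in H3K4me3 and 0.992 and 1.02 in H3K27me3. H3K9me3 had the fewest enriched peaks of the marks, so these values come from the whole list.

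Runs of peaks without reads appeared in 5 of the 7 knockouts and in both ChIPmentation clones, and in none of the ARID1A knockout, the ARID1B knockout and the wild-type ChIP-seq libraries. SMARCC1 knockout cells had 6 runs with 47 peaks over 1150 kb (897.5 reads expected), SMARCA2 knockout cells 4 runs with 21 peaks over 262 kb (472.1 expected), SMARCC2 knockout cells 2 with 10 peaks, and BCL7B and SMARCA4 knockout cells 1 each. The longest lay on chromosome 9, 82511257 to 82975104, in SMARCC1 knockout cells, with 18 peaks and 319 reads expected. A stretch of chromosome 16 recurred, at 78554409 to 78830545 in SMARCC1 knockout cells and again in clone 1102-3, at 78830044 to 79100975 in SMARCA4 knockout cells and at 78512272 to 78583399 in SMARCA2 knockout cells. The wild-type clone 921-7 lacked 12 peaks on chromosome 6, 163026877 to 163149232, where 3924 reads were expected.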
